A study of Mus musculus with 12 samples.

How the data were processed

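RNA was measured in primary neurosphere cultures, free-floating clusters of neural progenitor and stem cells, grown from the hypothalamus of C57Bl/6 mouse fetuses at embryonic day 14.5. At passage 3 the cultures received 100 nM dexamethasone, a synthetic glucocorticoid, or ethanol vehicle for 4 hours. The labels give 4 groups, male and female cultures under either treatment, with 3 biological replicates in each and 12 libraries in all. Libraries were made from total RNA with a stranded kit. Each library was run on several sequencing lanes, and the table used here holds 1 column per library. How a biological replicate was defined is not given in the sources used here, so the p-values measure the spread between these cultures.

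The authors deposited FPKM values, fragment abundances scaled by transcript length and library size, for 40597 loci. Per the submitters' processing notes, the tools were TopHat2 2.0.9, Cufflinks 2.2.1 and Cuffdiff 2.2.1 on the GRCm38 build. The annotation release, strand setting and scaling between libraries are not given in the sources used here, so overlapping and antisense genes are uncertain. A gene name was present for 37937 loci, and 930 loci joined more than 1 gene. Names that a spreadsheet had turned into dates were restored for 24 loci through their Ensembl identifiers. Coordinates are those of GENCODE M21 on GRCm38, matched by Ensembl identifier for 35496 loci and counted from 1. No authors' tests were part of the table, so none are described.

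FPKM carry no counts, so the absolute depth is unknown. At small RNA loci with low values, the ratio between libraries clustered at 1 value per library within a log ratio of 0.005. Relative to male vehicle library 3, the value of 1 fragment by this measure lay between 1 and 1.61. The clusters held as few as 7 loci, so this is a rough guide to relative depth. Summed over protein-coding loci, the libraries held 397412 to 453923 FPKM.

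An exact 0 in this table can be a failed estimate. The mitochondrial ribosomal RNA locus mt-Rnr2, which every cell uses, is listed at 0 in all 12 libraries. At 51 tested loci every library of at least 1 group is at 0 while every library of another group is at 5 FPKM or more. For any gene with a whole group at 0, no fold change is given and the library values are stated.

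Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 12 libraries, contrasts, eBayes with a mean-variance trend). Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05 and no fold threshold. Loci with a mean of at least 1 FPKM over the 12 libraries were kept, which left 14931 loci. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The contrasts were the effect of dexamethasone in males, in females and averaged over both, the interaction (female effect minus male effect), and the difference of the sexes under each treatment. Every adjusted p in the text is from limma.

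The code was tested on simulated log2 values with 200 changed loci among 14880. For the male effect it recovered 20% of changes of 0.5, 48.5% of changes of 1 and 83.1% of changes of 2 on the log2 scale. For the female effect these shares were 14.3%, 53.6% and 82.4%. For the averaged effect they were 37.3%, 88.6% and 84.1%, and for the interaction 9.86%, 26.8% and 56.9%. The simulated noise was drawn independently for each library. In the data, same-numbered libraries of a sex resembled each other, so these shares may not hold for the real fits.

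The replicate numbers come from the labels, which do not say that libraries with the same number share a culture, litter or day. The main models therefore hold no term for the number, and fits with it as a block are given as alternatives. For the effects of dexamethasone and the interaction the block was the number within each sex. For the comparisons of the sexes it was the number alone, shared by males and females.

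Before the data were examined, 30 gene lists were fixed: glucocorticoid-induced genes, inflammatory NF-kB targets, glucocorticoid receptor machinery, sex steroid signalling, proliferation, growth arrest, immediate early genes, MAPK feedback, Notch, neural stem cells, hypothalamic patterning, telencephalic genes, neuropeptides, neuronal, astrocytic, oligodendrocyte lineage, microglial, endothelial, mural and fibroblast, erythroid, pituitary and ependymal markers, circadian clock, cholesterol synthesis, integrated stress response, heat shock, hypoxia and glycolysis, extracellular matrix, Y-linked genes and genes escaping X inactivation. The 21 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a contrast, with an estimated correlation and fry as alternatives.

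Named genes follow a rule fixed at the same time. For each effect of dexamethasone these are the 12 largest rises and 12 largest falls past the threshold with every treated library beyond every vehicle library. The interaction has no such library condition, and the sex comparisons take the 10 largest in each direction. Members of the glucocorticoid-induced list, both corticosteroid receptors, Xist and the Y-linked genes are named in any case. For each list described, the members with the smallest p are named. Alternatives covered the pseudocount, the filter, rescaling, quantile normalization, the replicate number as a block, fits on only the groups compared, robust and weighted fits, other thresholds and each library left out in turn. Fits without these 51 loci, and fits on protein-coding loci without them, were added after seeing the data.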

Results

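The series holds 12 RNA libraries of mouse hypothalamic neurospheres from embryonic day 14.5, in 4 groups of 3: male and female cultures treated for 4 hours with 100 nM dexamethasone or with vehicle. Loci above 1 FPKM numbered 13755 to 14826 per library. Protein-coding loci took 3.23% to 10.2% of all FPKM in a library. In male vehicle library 3, loci without a gene name took 75.0% of the FPKM, and in male dexamethasone library 2 they took 53.1%. In the other 10 libraries this share was 11.6% to 38.6%.

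Sex labels were checked with Xist, the RNA that silences an X chromosome, and with Y-linked genes. The Xist locus averaged 242 FPKM over the 6 female libraries and 2.88 FPKM over the 6 male libraries, and every female library was above every male library (exact two-sided permutation test, p = 0.00216, the smallest that 924 splits can give). This test takes the 12 libraries as independent, and the labels do not say whether same-numbered libraries share a culture. If they do, that p-value is too small. Ddx3y, an RNA helicase gene on the Y chromosome, stood at 18.3 ± 1.97 FPKM (SD, n = 3) in male vehicle cultures and at 20.3 to 22.6 FPKM in the 3 male dexamethasone libraries, and at no more than 0.0397 FPKM in any female library. Male dexamethasone library 2 had 14.1 FPKM of Xist and male vehicle library 2 had 3.04 FPKM, while the other 4 male libraries lay at or below 0.0466 FPKM.

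**Figure D1:**
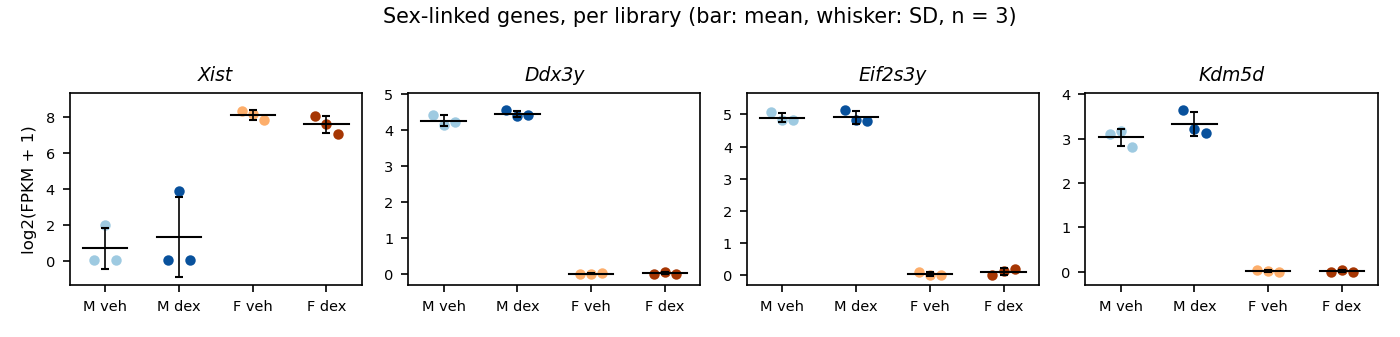
Xist, Ddx3y, Eif2s3y and Kdm5d in log2(FPKM + 1) for each library (points), with the mean (bar) and SD (whisker) of 3 libraries per group; M and F stand for male and female, veh and dex for vehicle and dexamethasone. The 6 male libraries lie above the 6 female libraries for the 3 Y-linked genes, and 2 male libraries show Xist, at 14.1 and 3.04 FPKM.

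The cultures expressed neural stem cell genes throughout. All 25 tested markers of that list averaged at least 1 FPKM, led by Fabp7, a fatty acid binding protein of radial glia, at 3503 FPKM. All 16 astrocytic markers and 14 of 17 oligodendrocyte lineage markers also reached 1 FPKM, with Apoe at 615 FPKM and Olig1 at 211 FPKM. Of 20 neuronal markers 10 did so, Map2 being the highest at 274 FPKM and Gap43 at 118 FPKM, while the median of the list was 1.07 FPKM. Dcx (0.581 FPKM), Rbfox3 (0.483 FPKM) and Gad2 (0.122 FPKM) were among those below 1 FPKM. Few markers of other tissues reached it: 1 of 15 microglial, 3 of 14 endothelial, 3 of 15 mural or fibroblast, 1 of 11 pituitary, 2 of 11 ependymal, 1 of 12 telencephalic and 0 of 9 erythroid genes. None of 21 neuropeptide genes reached 1 FPKM, and 5 of 28 hypothalamic patterning genes did.

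The comparison within males asks which transcripts respond to dexamethasone in male cultures. Fam107a, a gene of an actin-binding protein (chromosome 14, 8296274 to 8318023), rose from 0.175 ± 0.15 FPKM (SD, n = 3) to between 18.7 and 38.1 FPKM, a log2 fold change of 4.52 (SE 0.26, adjusted p = 2.71e-05). Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28399094 to 28517527), rose from 23.1 ± 2.38 to 116 ± 35.7 FPKM. The transcription factor gene Klf9 (chromosome 19, 23141226 to 23168134) rose from 6.74 ± 0.924 to 29.7 ± 1.03 FPKM (adjusted p = 1.03e-05). Zbtb16, another transcription factor gene (chromosome 9, 48654297 to 48836222), rose from 0.669 ± 0.419 to 11.1 ± 1.74 FPKM. Hif3a, a hypoxia-inducible factor subunit gene (chromosome 7, 17031507 to 17062427), rose from 0.0602 ± 0.0262 to 7.02 ± 1.63 FPKM. The other large rises were those of Ptk2b (log2 fold change 2.45), Tsc22d3 (2.37), Mfsd2a (2.17) and Ada (2.04), with adjusted p between 0.00242 and 0.0155. Armcx2 (chromosome X, 134804145 to 134809221) fell from 20.9 ± 0.645 to 14.2 ± 0.516 FPKM (adjusted p = 0.00717).

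In all, 47 of 14931 loci were called in males, 43 higher and 4 lower. Of these, 5 had a whole group at 0 and another whole group at 5 FPKM or more: mt-Rnr1, Lars2, n-R5s160, Rn7sk and mt-Tf. Rn7sk, the 7SK small nuclear RNA, is listed at 0 in all 6 dexamethasone libraries. In the vehicle libraries it is listed at 119415, 59637 and 57975 FPKM in males and at 86677, 91178 and 54643 FPKM in females. Gm25574 is listed at 0 in the 3 male dexamethasone libraries and at 2.07, 1.76 and 2.30 FPKM in the male vehicle libraries. Ptk2b was not called without male dexamethasone library 2 or male vehicle library 1 (adjusted p = 0.0618 and 0.0602), and Tsc22d3 not without male vehicle library 1, 2 or 3 (0.0602, 0.0612 and 0.0748). Mfsd2a was not called without male dexamethasone library 1 (0.0553) or male vehicle library 1, 2 or 3 (0.0613, 0.0788 and 0.0616). Gm25574 was not called without any 1 of the 6 male libraries or female dexamethasone library 1 (0.0606 to 0.113). Fitting only the male libraries gave 18 calls, without Ptk2b, Tsc22d3, Fkbp5, Mfsd2a, Ada, Armcx2 and Lars2 (adjusted p from 0.0548 to 0.328), and leaving out male vehicle library 1, 2 or 3 gave 29, 28 and 31 calls. With the replicate number as a block there were 148 calls, 95 higher and 53 lower.

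In females the same question was asked of female cultures. Fam107a rose from 0.0549 ± 0.019 to 30.4 ± 9.66 FPKM (SD, n = 3; log2 fold change 4.85, SE 0.26, adjusted p = 2.06e-05). Zbtb16 rose from 0.427 ± 0.168 to 12.4 ± 2.11 FPKM, Fkbp5 from 17.4 ± 3.11 to 109 ± 12.7 FPKM and Klf9 from 7.34 ± 0.633 to 32.4 ± 2.31 FPKM. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein (chromosome X, 140539528 to 140600659), rose from 14.2 ± 1.70 to 86.4 ± 21.1 FPKM (adjusted p = 0.00882). Further rises were those of Ptk2b (2.74), Hif3a (2.57), Ada (2.51), Mfsd2a (2.39), Tprn (2.14), the chloride channel gene Cftr (2.14) and Nedd9 (2.04), as log2 fold changes with adjusted p of at most 0.0108. Armcx2 fell from 20.7 ± 1.10 to 15.3 ± 0.331 FPKM, Rab8b from 23.6 ± 1.67 to 17.4 ± 0.746 FPKM and Zdhhc18, a palmitoyltransferase gene, from 41.0 ± 2.43 to 23.3 ± 1.80 FPKM.

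A total of 72 loci were called in females, 67 higher and 5 lower. Rn7sk and Gm24876 were among those lower and had whole groups at 0; Gm24876 is listed at 42.4, 44.5 and 77.9 FPKM in female vehicle libraries and at 0 in the other 9. Tsc22d3 was not called without female dexamethasone library 1 (adjusted p = 0.05002), and Nedd9 not without that library (0.0639) or female vehicle library 2 or 3 (0.0516 and 0.0551). Zdhhc18 was not called without female dexamethasone library 1 or 3 (0.0728 and 0.0640) or female vehicle library 2 or 3 (0.0678 and 0.0530). Armcx2 was not called without any 1 of the 6 female libraries or male vehicle library 2 (0.0515 to 0.114), and Rab8b was called only without female vehicle library 1 among the 12 fits with 1 library left out (up to 0.212) and not with no filter or a robust fit (0.0558 and 0.0502). Fitting only the female libraries gave 33 calls, without Mfsd2a, Nedd9, Armcx2, Rab8b and Zdhhc18 (0.0692 to 0.260), and leaving out female dexamethasone library 1 or 3 or female vehicle library 3 gave 31, 45 and 38. With the replicate number as a block there were 187 calls, 128 higher and 59 lower.

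Averaged over both sexes, the effect rests on 6 libraries against 6. Besides the genes above, Hspb1, a small heat shock protein gene, was higher by 2.82 on the log2 scale (SE 0.42, adjusted p = 0.00889) and the potassium channel gene Kcnn2 by 2.19 (adjusted p = 0.00457). Thrsp, a gene of lipid synthesis regulation, was also higher (averaged adjusted p = 0.0111), and went from 5.21 ± 2.24 to 30.4 ± 17.2 FPKM in females (SD, n = 3). Falls were smaller. Diras2 fell by 1.31, Rerg by 1.07, the phosphodiesterase genes Pde1b and Pde3a by 1.04 and 0.93, the chemokine receptor gene Cxcr4 by 1.01, and Scg2 by 0.93 on the log2 scale. Fbxo32 fell by 0.86, Gm9869 by 0.84, Arl4a by 0.82, Rprm by 0.71 and Uaca by 0.69, with adjusted p between 0.0041 and 0.0388 for these 11 genes. For example, Pde1b went from 50.1 ± 12.2 to 25.8 ± 6.98 FPKM in males and from 63.1 ± 7.10 to 28.4 ± 5.52 FPKM in females (SD, n = 3). The averaged effect called 229 loci, 171 higher and 58 lower. Uaca was not called without female vehicle library 3 or male vehicle library 2 (adjusted p = 0.0504 and 0.0503). With 1 library left out, Fbxo32 was called only without female dexamethasone library 1, female vehicle library 3, male dexamethasone library 1 or male vehicle library 3, and Scg2 only without female or male vehicle library 3 (up to 0.0894 and 0.109). Diras2 was then called only without female vehicle library 1, male dexamethasone library 2 or male vehicle library 1, and Gm9869 only without library 3 of female dexamethasone or male vehicle or library 2 of male dexamethasone (up to 0.0843 and 0.0956). With no filter, Diras2, Fbxo32 and Gm9869 were not called (0.0537 to 0.0629), nor were Fbxo32 and Scg2 with quantile normalization (0.0585 and 0.0862). Without female dexamethasone library 1 there were 146 calls. With the replicate number as a block there were 804 calls, 420 higher and 384 lower, so the balance of rises and falls depends on the model. Same-numbered libraries of a sex resembled each other, which the model without the block leaves out.

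Of 27 tested glucocorticoid-induced genes, 17 rose in the averaged effect, none fell and 10 were not called; adjusted over the list alone, 21 rose. In males 10 rose and in females 13, or 18 in each sex adjusted over the list alone. Besides Fkbp5, Tsc22d3, Klf9, Zbtb16, Hif3a and Fam107a, the averaged effect raised the clock gene Per1 by 1.91 on the log2 scale, the apoptosis inhibitor gene Bcl2l1 by 1.56, Errfi1 by 1.46 and Mertk by 1.80. Cebpd (1.86), Nfkbia (1.09), Bcl6 (1.19), Arrdc2 (0.96) and the metallothionein genes Mt1 (1.31) and Mt2 (1.78) were also called. Lcn2 is listed at 0 in all 6 vehicle libraries and at 7.15, 2.06 and 0.539 FPKM in the male and 4.47, 2.14 and 1.59 FPKM in the female dexamethasone libraries (adjusted p = 0.0436). Not called were Sgk1 (log2 fold change -0.18), Klf15 (0.94), Dusp1 (0.33), Cdkn1a (0.36), Cebpb (0.97), Ddit4 (0.78), Pdk4 (1.08), Angptl4 (-0.37), Arrdc3 (0.10) and Tgm2 (-0.26). Cebpb was called without female dexamethasone library 3 or male dexamethasone library 2 (adjusted p = 0.0304 and 0.0488). With 1 library left out, Mt1 was called only without female dexamethasone library 3, female vehicle library 1, male dexamethasone library 3 or male vehicle library 1 (up to 0.0805). Mt2 was then called only without female vehicle library 1, male dexamethasone library 3 or male vehicle library 1, and Lcn2 only without male dexamethasone library 3 (up to 0.102 and 0.121); without male dexamethasone library 1 its mean fell below the filter. With no filter, Mt2 and Lcn2 were not called (0.0635 and 0.0615), and Cebpb was called, among other settings, with a pseudocount of 0.1 or 0.5, robust or weighted fits, or protein-coding loci only (0.0215 to 0.0491). Arrdc3 turned negative without female vehicle library 3 (-0.00734), male dexamethasone library 1 (-0.00351) or male vehicle library 3 (-0.0639). The list stood above other genes in the male, female and averaged effects, with adjusted p of 7.59e-35, 4.14e-33 and 7.63e-32. With an estimated correlation these were 0.00786, 0.00934 and 0.0106. With an estimated correlation and the replicate number as a block, the list was not called (0.217, 0.436 and 0.258). The blocked fit leaves 4 residual degrees of freedom, against 8 without the block, which limits a test with an estimated correlation. With the block and the preset correlation, camera gave adjusted p of 3.31e-22, 1.62e-21 and 5.79e-20. In the averaged effect 20 members were then called higher and 0 lower, so the lost call does not show a missing response.

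**Figure D2:**
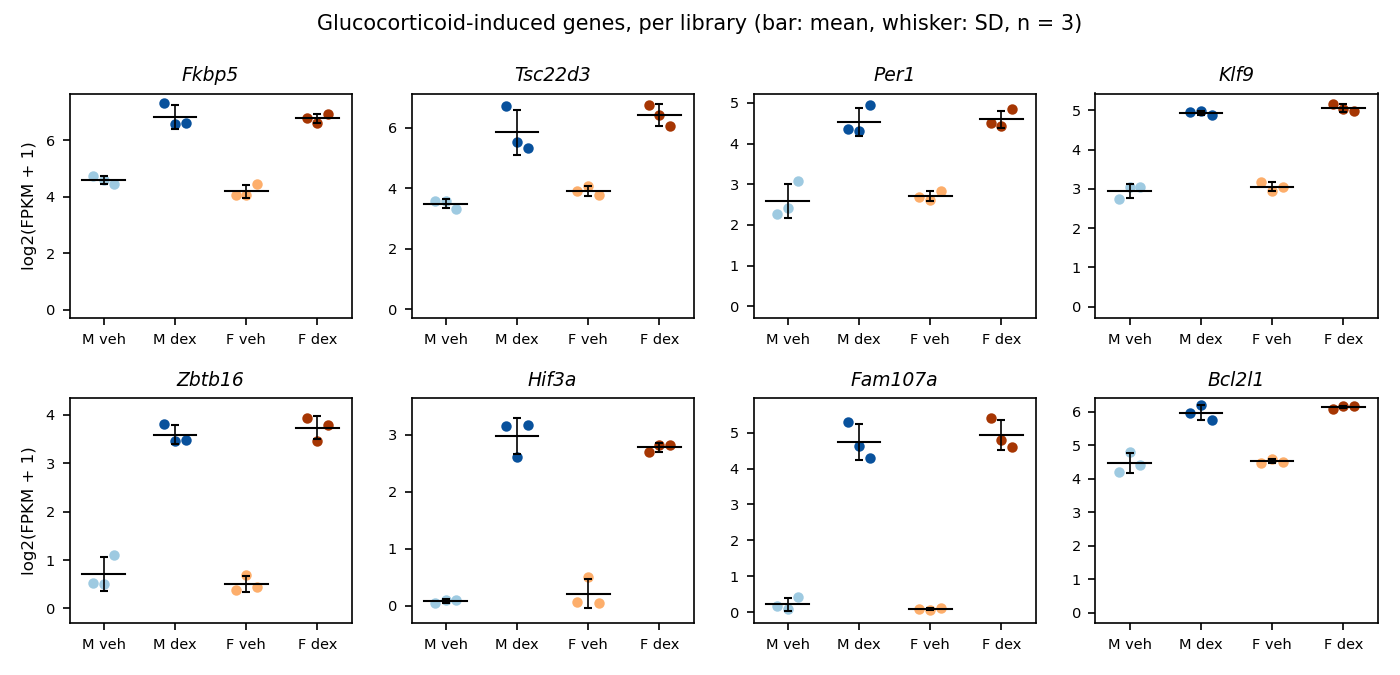
Values of 8 glucocorticoid-induced genes in log2(FPKM + 1) for each library (points), with the mean (bar) and SD (whisker) of 3 libraries per group; M and F stand for male and female, veh and dex for vehicle and dexamethasone. Every dexamethasone library lies above every vehicle library of its sex, as for Fkbp5, which averaged 23.1 and 116 FPKM in males and 17.4 and 109 FPKM in females.

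The glucocorticoid receptor gene Nr3c1 averaged 18.5 ± 2.09 FPKM in male vehicle and 15.6 ± 1.02 FPKM in male dexamethasone cultures, and 20.3 ± 1.10 and 18.1 ± 3.24 FPKM in the female groups (SD, n = 3; averaged adjusted p = 0.375). Nr3c2, the mineralocorticoid receptor gene, averaged 0.993 to 1.64 FPKM over the groups.

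Other lists moved less. Neural stem cell genes were lower as a group in the averaged effect (adjusted p = 0.0159), with 3 of 25 members called lower, Msi1 (-0.64), Egfr (-0.35) and Nr2e1 (-0.57), and none higher; adjusted over the list alone, 5 were lower. Immediate early genes were lower (adjusted p = 0.0159), with Jun, in a locus joined to Gm12703, at -0.65 and Klf4 at -0.63 called among 24; adjusted over the list alone, 4 were lower and 1 was higher. Growth arrest genes were higher (adjusted p = 0.0236), with Sesn1, a stress-response gene, the only call among 22, at 1.47; adjusted over the list alone, 4 were higher. With an estimated correlation none of the 3 held (adjusted p = 0.0854, 0.766 and 0.421). The correlation estimated for neural stem cell genes was -0.00975, below the preset 0.01. With fry these genes were lower in the averaged effect, males and females (adjusted p = 0.00239, 0.0214 and 0.0234). Immediate early and growth arrest genes were not called with fry in the averaged effect (0.286 and 0.0605) or in either sex. With camera at the preset correlation, the 3 lists had adjusted p of 0.0191, 0.0263 and 0.0191 in males, and with an estimated correlation adjusted p = 0.103, 0.800 and 0.349. In females they had 0.0237, 0.0242 and 0.0797, and with an estimated correlation adjusted p = 0.140, 0.697 and 0.695. Also in females, proliferation genes (adjusted p = 0.00789) and cholesterol synthesis genes (adjusted p = 0.0237) were higher as groups with no member called. With an estimated correlation their adjusted p were 0.700 and 0.697.

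With 1 library left out, Egfr was called only without female or male vehicle library 1, and Nr2e1 only without female dexamethasone library 3 or female vehicle library 1 (averaged adjusted p up to 0.128 and 0.125). Jun was then called only without female dexamethasone library 1, female vehicle library 2, male dexamethasone library 3 or male vehicle library 1, and Klf4 only without female vehicle library 2 (up to 0.0995 and 0.105). With no filter Egfr, Jun, Klf4 and Nr2e1 were not called (0.0544 to 0.0968), nor were Klf4 and Nr2e1 with quantile normalization (0.0523 and 0.0702) or Nr2e1 with a mean of at least 5 FPKM (0.0742). Leaving out 1 library ended most of the list calls. Neural stem cell genes stayed called in the averaged effect without each library (camera, adjusted p up to 0.0408). In the averaged effect, immediate early genes were not called without female vehicle library 1 or male dexamethasone library 1 (adjusted p = 0.101 and 0.134), and growth arrest genes not without these (0.0713 and 0.0564) or male vehicle library 3 (0.0667). In males, neural stem cell genes were not called without vehicle library 1 (0.0621), immediate early genes not without dexamethasone library 1 or vehicle library 2 (0.778 and 0.159), and growth arrest genes not without dexamethasone library 1 or vehicle library 3 (0.132 and 0.172). In females, neural stem cell genes were not called without dexamethasone library 2 or 3 or vehicle library 1 (0.0707, 0.0904 and 0.0844), and immediate early genes not without these or vehicle library 3 (0.0904 to 0.328). Proliferation genes were not called there without dexamethasone library 3 or vehicle library 1 or 2 (0.416, 0.0844 and 0.445), and cholesterol synthesis genes not without dexamethasone library 3 or vehicle library 1 (0.598 and 0.222). The averaged effect called 4 lists, 2 without female vehicle library 1 and 7 without female vehicle library 3. In females 5 lists were called, 3 without dexamethasone library 2 and 1 without dexamethasone library 3 or vehicle library 1.

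Several single members of lists without a group-wide shift rose in the averaged effect. Among astrocytic markers these were the connexin gene Gjb6 (2.17) and the locus of Glul, the glutamine synthetase gene (1.16), among clock genes Per2 (0.81), and in the Notch list Lfng (0.90). Cspg4 of the oligodendrocyte lineage rose by 0.76 and Adm of the hypoxia and glycolysis list by 1.02. With 1 library left out, Glul was called only without female dexamethasone library 3, female vehicle library 2 or male dexamethasone library 2 (up to 0.0803 as adjusted p), and Per2 was not called without male dexamethasone library 2 or male vehicle library 1 (0.0547 and 0.0522). Hspb1 was the called member of the heat shock list and Errfi1 that of the MAPK feedback list. No member was called in the averaged effect among inflammatory NF-kB targets, receptor machinery, sex steroid signalling, extracellular matrix, integrated stress response, neuronal, hypothalamic patterning and X-escaping genes. As groups, none of these lists passed in the averaged effect, nor did proliferation and cholesterol synthesis genes, with adjusted p from 0.0716 for Notch genes to 0.938 for X-escaping genes. With the replicate number as a block, Notch and hypothalamic patterning genes were lower as groups (camera, adjusted p = 0.0319 for each). With an estimated correlation as well, they were not (0.721 and 0.392). The other 9 lists had fewer than 5 tested members and were not tested: telencephalic, neuropeptide, microglial, endothelial, mural and fibroblast, erythroid, pituitary, ependymal and Y-linked genes.

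Whether dexamethasone acts differently in the sexes was tested by the interaction. It called 5 loci, mt-Rnr1, mt-Tf, Lars2, Gm24876 and n-R5s160, and each of them has whole groups at 0. mt-Rnr1 is listed at 23225, 26291 and 26810 FPKM in the male dexamethasone libraries and at 0 in the other 9, and mt-Tf at 210, 242 and 284 FPKM in the male vehicle libraries only. n-R5s160 is listed at 12.9, 13.9 and 18.1 FPKM in male dexamethasone libraries only. Lars2 is listed at 0 in the 3 male vehicle libraries and at 503, 6604 and 2524 FPKM under dexamethasone in males. In females it is listed at 1968, 638 and 661 FPKM under vehicle and 2071, 2222 and 1578 FPKM under dexamethasone. Without the 51 loci that have a whole group at 0 and another whole group at 5 FPKM or more, limma called 0 loci, an alternative chosen after seeing the data. Over all loci, 219 had an unadjusted p under 0.05, where 747 would by chance. With the replicate number as a block 8 loci were called, all among those 51. The test without a block gave fewer small p-values than chance would, so the few calls do not exclude differences at single loci. It took same-numbered libraries as independent, though they resembled each other. Its p-values may be too large for that reason, which was not tested. Lars2 was not called without female dexamethasone library 3 or male vehicle library 3 (adjusted p = 0.0745 and 0.0584). Leaving out female dexamethasone library 2 gave 10 calls, female vehicle library 1 or 2 gave 14 and 11, male dexamethasone library 1 or 3 gave 10 and 9, and male vehicle library 1 gave 8. Zdhhc18, called in females, had an interaction of -0.77 on the log2 scale (SE 0.16), which failed the correction (adjusted p = 1.00), and stood at 27.2 ± 2.92 and 26.7 ± 3.37 FPKM in male vehicle and dexamethasone cultures. As groups, proliferation genes (adjusted p = 7.81e-07) and cholesterol synthesis genes (adjusted p = 0.00723) had higher fold changes in females than in males, with no member called; with an estimated correlation both adjusted p were 0.998. Proliferation genes were not called without female vehicle library 2 (adjusted p = 0.0767), and cholesterol synthesis genes not without female dexamethasone library 3, female vehicle library 1 or 2, male dexamethasone library 1 or male vehicle library 2 or 3 (0.0594 to 0.887). The 2 called lists became 4 without male dexamethasone library 3.

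Fold changes in males and females were compared across loci, which are not independent replicates, and the comparisons share no libraries. Over all 14931 loci Pearson's r was 0.25 and Spearman's rho 0.49. Over 10636 protein-coding loci, those tested other than Lars2, a set chosen after seeing the data, r was 0.74 and rho 0.64. Leaving out the same 51 loci, all 40 loci called higher in males were also called higher in females, where 67 were called and 0.18 would be shared by independent lists. Of the other loci called lower, 2 in males, Armcx2 and Gm25574, and 3 in females, 1 was shared, Armcx2. The calls of both sexes use 1 spread per locus, estimated from all 12 libraries, so the lists of calls are not independent of each other.

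**Figure D3:**
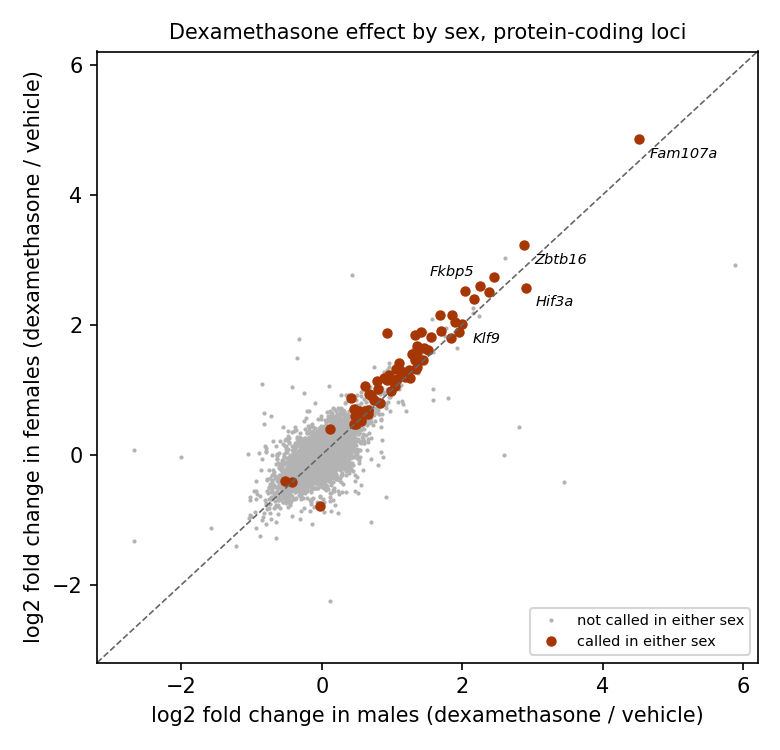
Log2 fold change of dexamethasone against vehicle in males (horizontal axis) and females (vertical axis) for 10636 protein-coding loci, those tested other than Lars2; the 66 loci called in either sex are drawn as large points and the dashed line marks equal change. Fam107a lies farthest out among the called loci, at 4.52 in males and 4.85 in females.

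Between the sexes, Y-linked genes made up the male-higher calls that had no group at 0. Under vehicle, Eif2s3y was at 29.0 ± 2.93 FPKM in males and 0.0266 ± 0.0461 FPKM in females (SD, n = 3), Uty at 11.7 ± 0.744 and 0.303 ± 0.0587 FPKM and Kdm5d at 7.24 ± 1.04 and 0.00984 ± 0.00968 FPKM. Xist (log2 difference 7.44, SE 0.94, adjusted p = 0.0224) and Kdm6a, which escapes X inactivation, were higher in females, Kdm6a at 14.3 ± 1.32 against 9.20 ± 0.379 FPKM (adjusted p = 0.0302). Of 11 loci called under vehicle, 5 had a group at 0: Lars2, Gm24876, mt-Tf and 2 loci that include Gm26917, listed at 0 in all 6 male libraries. The locus of Gm26917 and AY036118 is listed at 681, 891 and 774 FPKM in the female vehicle and 625, 592 and 759 FPKM in the female dexamethasone libraries. The locus of Gm26917 and Gm26924 is listed at 5750, 1663 and 2241 FPKM and at 5941, 6073 and 4432 FPKM. Under dexamethasone 10 loci were called, again with Ddx3y, Eif2s3y, Uty and Kdm5d higher in males, and with the escaping gene Eif2s3x higher in females at 132 ± 5.67 against 85.9 ± 3.23 FPKM (adjusted p = 0.0443). mt-Rnr1, n-R5s160, Gm25574 and the 2 loci with Gm26917 were the others, each with a group at 0. Xist had a log2 difference of 6.26 under dexamethasone and was not called there (adjusted p = 0.0790), but was without male dexamethasone library 2 (7.55, adjusted p = 0.000503, the lowest over all alternatives, which reached 0.972). Leaving out female vehicle library 1 gave 23 calls under vehicle, and fitting only the vehicle libraries gave 20. Under vehicle, Xist was not called without any 1 of the 6 female libraries or male vehicle library 1 or 3 (0.0572 to 0.134), nor with a pseudocount of 0.1 or 0.5 or sample weights (0.296, 0.0602 and 0.0892). Kdm6a was called only without female vehicle library 1 when 1 library was left out (up to 0.180), and Eif2s3x under dexamethasone only without female vehicle library 1 or male vehicle library 2 or 3 (up to 0.206). Gm25574 under dexamethasone was called only without female vehicle library 1 (up to 0.216). Kdm6a was not called with median-ratio rescaling, quantile normalization, no filter, the vehicle libraries alone, protein-coding loci alone or the 51 loci left out (0.0505 to 0.727). Eif2s3x and Gm25574 were not called, among other settings, with median-ratio rescaling, the dexamethasone libraries alone or the 51 loci left out (0.0581 to 0.0727), nor Gm25574 with no filter (0.0769).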

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

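All tests in this part were chosen after results were seen, except the splits for the sexes under each treatment; those for males, females, the averaged effect and the interaction took the place of splits that kept same-numbered libraries apart, whose results had been seen. The interaction of sex and dexamethasone marked 5 loci as differing between the sexes: mt-Rnr1 (adjusted p = 1.06e-13), mt-Tf (3.93e-09), Gm24876 (1.74e-05), n-R5s160 (5.57e-05) and Lars2 (0.0136, and 0.0745 and 0.0584 without female dexamethasone library 3 or male vehicle library 3). All 5 have a group with every library at exact 0, which is consistent with estimates that failed for a whole group. A sex-dependent change of all mitochondrial transcription in the direction of mt-Rnr1 was predicted to reach the mitochondrial protein-coding loci. Their interaction was then predicted at -1 or below, and the lowest was -0.047 (mt-Co1, SE 0.289). This argues against such a general change as the cause for mt-Rnr1. A change of the ribosomal RNA alone was not tested. An earlier form of this test, the largest interaction of either sign (0.57, mt-Nd2), decided nothing. For the other 4 loci a difference between the sexes remains untested.

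Regrouping the libraries bore on the counts of called loci. For the averaged effect, 1 of 100 splits drawn from 200 within the sexes gave as many calls, the real one with 229, and the highest other gave 8. This argues against chance for the count as a whole, not for each called locus. The other splits mix treated and vehicle libraries, which widens their spread and can lower their counts. For the interaction, 31 of 100 ways drawn from 200 of giving the libraries of each treatment to the sexes reached the real count of 5. The real grouping keeps same-numbered libraries of a sex together, while a regrouping can place them in different sexes. The share therefore cannot decide on chance, which is not excluded. The highest other gave 1487 calls, which points to a structure of the samples. In that regrouping the dexamethasone and vehicle libraries of the same sex and number were always given to opposite sexes. Both libraries of such a pair thus entered the interaction with the same sign. For males (47 calls) and females (72 calls) the highest others were 9 and 4 among 10 splits, and for the sexes under vehicle (11 calls) and dexamethasone (10 calls) they were 6 and 4 among 10. Those 10 splits are too few for a share under 0.05.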

How the results depend on the processing

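The fits without the 51 loci listed at 0 in a whole group and at 5 FPKM or more in another, and on protein-coding loci without them, were chosen after seeing the data, and the other alternatives before. Over all alternatives, single named genes gave 2649 values with the direction and side of the threshold reported, 251 with a lost call, 20 with a gained call and 3 with a changed sign; lists gave 318 and 57 lost. Among called named genes, 8 of 16 in males, 11 of 17 in females, 33 of 47 averaged, 4 of 5 in the interaction, 9 of 11 between the sexes under vehicle and 8 of 10 under dexamethasone were called under every alternative that tested the locus. A fit that left a locus out was not counted for it. The fits without the 51 loci thus do not count for loci such as mt-Rnr1 and mt-Tf, and they held 0 interaction calls. The cause of the moves was not tested. Fits on fewer loci did not always call fewer. Protein-coding loci alone gave 50 calls in males, 96 in females and 273 averaged, against 47, 72 and 229. FPKM carry no counts, so no limit from depth could be given, and the planned comparisons of single lanes and of the authors' own tests were not run.

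The labels do not say that a replicate number is shared by a culture, and over all tested loci the deviations of same-numbered libraries within a sex correlated by 0.0819 to 0.167, with 2 of 6 pairs below 0.1. Over protein-coding loci, chosen after seeing the data, they correlated by 0.334 to 0.584, and different numbers by -0.455 to -0.102. In both sets every library correlated best, within its sex, with its own number under the other treatment, a link not in the labels. With the replicate number as a block, the calls were 148 in males (95 higher, 53 lower), 187 in females (128 and 59), 804 averaged (420 and 384) and 8 for the interaction. Higher loci were 52.2% of the averaged calls with the block and 74.7% without. Of the glucocorticoid-induced genes 20 rather than 17 were then called higher in the averaged effect, 12 rather than 10 in males and 14 rather than 13 in females. Those gained in the averaged effect were Klf15 (adjusted p = 0.0213, over all alternatives 0.00388 to 0.505), Dusp1 (0.0423, 0.0200 to 0.462) and Cebpb (0.0274, 0.00468 to 0.148), and on protein-coding loci alone with the block also Cdkn1a (0.0327, up to 0.676), Ddit4 (0.0138, up to 0.534) and Pdk4 (0.0289, up to 0.555). Not called with the block were Lars2 in the interaction (0.153, over all alternatives 0.000198 to 0.153), Gm25574 in males (0.0645, 0.000376 to 0.113) and under dexamethasone (0.154, 0.000215 to 0.218), and Eif2s3x (0.0625, 0.0341 to 0.206). With the block and an estimated correlation, the glucocorticoid-induced list was not called (adjusted p = 0.217 in males, 0.436 in females and 0.258 averaged). The blocked fit leaves 4 residual degrees of freedom, which limits that test. At the preset correlation the blocked adjusted p from camera were 3.31e-22, 1.62e-21 and 5.79e-20. The block together with leaving out these 51 loci gave 139, 183, 793 and 0, with 5 and 4 between the sexes under vehicle and dexamethasone. The block on protein-coding loci gave 353, 373, 1408 and 0, with 4 and 5 between the sexes and a correlation of 0.738.

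Without a block, leaving out these 51 loci gave 0 interaction calls (limma) and 5 and 4 calls between the sexes under vehicle and dexamethasone. Over all loci, 219 had an unadjusted interaction p under 0.05 without a block, where 747 would by chance. Protein-coding loci without a block gave 0, 4 and 5 and a correlation of 0.738, against 0.495 as Spearman's rho over all loci. Only the groups compared gave 18 calls in males, 33 in females and 20 between the sexes under vehicle; sample weights gave 95 in males, and an adjusted p under 0.1 gave 80 in males and 361 averaged. An estimated correlation left 1 list each in males, females and the averaged effect and 0 in the interaction; fry called 2, 2 and 0 in males, females and the interaction. Lists in females were 3 with a mean of at least 5 FPKM and 2 with quantile normalization, which left 1 in the interaction. Leaving out each library gave 28 to 49 calls in males, 31 to 74 in females, 146 to 215 averaged, 4 to 14 for the interaction, 9 to 23 and 8 to 14 between the sexes under vehicle and dexamethasone, a correlation of 0.183 to 0.288, a log2 difference of Xist of 6.65 to 7.43, and 3 to 6, 1 to 6, 2 to 7 and 0 to 4 lists in males, females, averaged and interaction. Arrdc3 averaged changed sign without female vehicle library 3 (-0.00734), male dexamethasone library 1 (-0.00351) and male vehicle library 3 (-0.0639), with up to 0.260 without male vehicle library 1.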

Other observations

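All tests in this part were chosen after the results were seen. Some genes of regional identity differed between libraries. Those named here were chosen after their values were seen, and no test between libraries of different numbers was run. Six3, a forebrain patterning gene in a locus joined to its antisense RNA, was at 0.0702 FPKM in female dexamethasone library 2 and 0.064 FPKM in female vehicle library 2, and at 7.45 to 50.6 FPKM in the other 10 libraries. Emx2, a gene of cortical and hypothalamic patterning, was at 0.268 and 0.234 FPKM in the same libraries and at 0.602 to 10.6 FPKM elsewhere, and Foxd1 was listed at 0 in both. Nkx2-1, a ventral hypothalamic patterning gene, stayed at or below 0.149 FPKM in all 12 libraries. The astrocyte intermediate filament gene Gfap ranged from 1.15 FPKM in male libraries 3 of both treatments to 78.0 FPKM in male dexamethasone library 1.

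The correlation of the fold changes in males and females was low over all loci, at 0.25. Over 1193 loci under 300 bp r was 0.021, and over 11129 loci of at least 1000 bp it was 0.75, which is consistent with noise of short loci with few fragments. Effects that differ between the sexes stay open: 219 loci of the model without a block had an unadjusted interaction p under 0.05 where 747 would by chance, which does not exclude differences at single loci.

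Xist in the male libraries numbered 2 amounted to 6.98% of the female dexamethasone mean in the dexamethasone library and 1.07% of the female vehicle mean in the vehicle library. Y-linked genes in male dexamethasone library 2 were at 101% of the mean of the other male libraries, which argues against a swapped sex label. Female cells in a culture from which both libraries came may account for the signal and would give like shares, but the shares differed 6.51-fold. The labels do not say that the libraries shared a culture, and an uneven division could give such a ratio, so this cannot be told apart from other sources. No other biological explanation was tested.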
